A study of Escherichia coli with 4 samples.

How the data were processed

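The series holds 4 RNA-seq libraries of E. coli, 2 from cultures exposed to NaHCO3 and 2 from control cultures exposed to NaCl, grouped and numbered by their sample titles. Per the labels, cells were collected cold after the exposure, ribosomal RNA was depleted, cDNA was made with random primers, and libraries were read as pairs of 100 nt on a HiSeq instrument. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

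One deposited table covers the whole series. The authors counted reads per gene, and per the file headers these are whole-number counts for each gene feature of a GenBank chromosome annotation. Their total is 10378738 and 9798727 for NaHCO3 replicates 1 and 2, and 11105224 and 10510877 for NaCl replicates 1 and 2. The authors also deposited RPKM values, which are the counts scaled by gene length and by a library total slightly above the column sum (10558014, 9955942, 11261426 and 10691762 in the same order). A further deposited score, headed CPM, is the count scaled to rescaled library sizes, so that its columns sum to between 918970 and 1081700. The sizes behind it lie within 99.9% to 100.2% of the effective sizes computed here. The deposited log2 ratio and mean log2 abundance, and the p-value and false discovery rate per gene, are the authors' own comparison. The aligner, the counting tool, their versions, the use of strand and the tool of the authors' test are not given in the sources used here.

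The counts were used for every test, since the RPKM and rescaled values are derived from them. The tests were run in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1: TMM scaling factors (0.932 and 0.924 for NaHCO3, 1.09 and 1.07 for NaCl), edgeR's default filter on low counts, a quasi-likelihood fit on group alone, and a two-sided test with Benjamini-Hochberg adjustment at 0.05. The filter kept 4835 genes and left out 87, and no gene was at 0 in all libraries. CPM printed in the text are counts scaled to TMM-adjusted library sizes, as mean ± SD over 2 libraries, and the SE of a log2 change is its size divided by the square root of the test's F value. The common dispersion was 0.00771, a biological coefficient of variation of 8.78%. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so none is reported for single genes. A floor of 3 counts per library was used for the gene with 0 counts in a group, and such floors cover counting error only.

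Gene symbols were taken from the deposited annotation (604 loci, 593 distinct symbols, 10 of them on several loci). The K-12 MG1655 gene table (assembly ASM584v2) matched none of the locus tags and 557 of the 593 symbols, and was used only for which genes neighbour each other there. Before the data were examined, 36 gene lists with 660 genes, the tests and the rule for named genes were fixed. The rule took the tna genes, the 10 genes with the largest rise and the 10 with the largest fall among those with a symbol, past the threshold, separated between groups and with a mean of at least 10 CPM in the higher group, and up to 4 members of each list past the set test and of both iron lists, by size of change in the direction of the list. That gave 33 genes. Of the lists, 22 had at least 3 tested members and were tested with camera (correlation 0.01), with camera on an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. A further 12 had 1 or 2 tested members and 2 had none: NADH dehydrogenase and terminal oxidases, and ribosomal RNA. Stretches of at least 5 consecutive tested genes called in 1 direction were listed after seeing the data, which gave 29 higher stretches with 217 genes and 27 lower ones with 197.

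The replicates of a group differed by more than sampling noise, with a chi-square per gene of 16.2 between the NaHCO3 libraries and 8.95 between the NaCl libraries, so none was treated as a library deposited again. This does not show that they came from separate cultures. The tests were checked on simulated counts for the NaHCO3 against NaCl comparison, with 4829 genes in the run and 200 changed genes. Of 50 genes changed at each size, the test recovered 64% at 1.5-fold, 88% at 2-fold and 100% at 4-fold and at 8-fold. Over 20 further draws, 6.41% of calls on average were unchanged genes (2.56% to 9.81%), somewhat more than the threshold of 0.05 states. In the data 1465 genes were called, far more than the 200 changed here, so this share does not carry over to those calls. A list shifted by 0.5 log2 was recovered, and 0 of the other lists were called. Genes were drawn independently, so this does not test camera on genes that vary together.

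The alternatives were a replicate block, leaving out each library in turn, DESeq2 1.42.0, its size factors in edgeR, total-count scaling, a filter at a mean of 50 counts or none, a log2 change of at least 1, and the other set tests. Figures were drawn with matplotlib 3.10.9. The sequences of the genes were not analysed here.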

Results

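RNA was measured by sequencing in Escherichia coli grown in LB medium and exposed in the logarithmic phase to 40 mM NaHCO3 for 40 min, and in control cultures given 40 mM NaCl for the same time. Bicarbonate is described in the series title as a potentiator of antibiotics, and the NaCl arm matched the added salt, on top of the 170 mM NaCl that the medium already held. Each group had 2 libraries. Over 4922 annotated genes, the NaHCO3 libraries held 10378738 and 9798727 counts and the NaCl libraries 11105224 and 10510877. Across genes, the log2 values of the libraries correlated at r = 0.992 within NaHCO3, at 0.994 within NaCl and at 0.970 to 0.975 between groups, where genes are not independent replicates. Of the 4922 genes, 604 carried a gene symbol in the deposited annotation, so most changed genes have none. Gene positions are those of the single chromosome of that annotation, whose locus tags begin with E2348C, and the strain of the cultures is not named in the labels.

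The first question was which genes differed after 40 min of bicarbonate. With NaHCO3, 759 genes were higher and 706 lower out of 4835 tested, and 104 of the higher and 149 of the lower genes differed by at least 1 on the log2 scale. Among called genes with a symbol, 167 were higher and 65 lower, so genes with a symbol leaned higher more than all genes did. The steepest rise among genes with a symbol was that of tnaA, tryptophanase, which splits tryptophan into indole, pyruvate and ammonia, at 9.59-fold. The deepest falls among genes with a symbol were those of hycE and hycD, subunits of the hydrogenase of the formate hydrogenlyase complex, at 19.0-fold and 18.9-fold, and of hdeB, a periplasmic chaperone active in acid, at 7.96-fold. In every one of these 1465 genes both NaHCO3 libraries lay on one side of both NaCl libraries. Such separation was found in 67.7% of all tested genes, where chance gives 33.3%. These are calls of edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment. With libraries scaled to their total counts alone, 358 genes were higher and 1574 lower (18.5% of calls higher, against 51.8%). That scaling moved the median log2 change of all genes from -0.04 to -0.25, a shift of 0.21.

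Higher and lower genes were counted by abundance, over 10 groups of tested genes ordered by mean CPM. Among the 484 genes of the most abundant group, 240 were higher and 35 lower, with a median log2 change of 0.25. Among the 484 genes of group 3 from the bottom, 29 were higher and 83 lower, with a median of -0.17. With total-count scaling these medians were 0.04 and -0.38. These groups were formed after seeing the data.

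The tryptophanase operon, named in the series title, was represented by tnaA alone among symbols (locus E2348C_RS21545, 4186053 to 4187468, plus strand). Its normalised read count was 3349 ± 772 CPM with NaHCO3 and 349 ± 43.3 CPM with NaCl (SD, n = 2 each), a log2 change of 3.26 ± 0.16 (SE; adjusted p = 3.19e-06, edgeR's quasi-likelihood test). Its neighbours without a symbol were chosen after their values were seen. The short gene just upstream, E2348C_RS21540 (4185758 to 4185832), rose by a log2 change of 3.44 ± 0.20, and the gene just downstream (4187604 to 4188806) by 1.91 ± 0.15. The next genes on the same strand rose by 1.22 ± 0.12 and 0.76 ± 0.12, and the one after those, at -0.20 ± 0.10, did not pass. In the K-12 MG1655 annotation, tnaA lies between tnaC, the leader peptide gene, and tnaB, a tryptophan permease gene, but the deposited table gives no symbol to the flanking loci. The whole series of neighbours higher with NaHCO3 spanned 9 genes from 4181817 to 4191047, with a median log2 change of 0.76. The list was 1 of 1 tested member higher, also when adjusted over the list alone, and since the study named tryptophanase from these samples, that is not independent evidence of direction.

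Iron acquisition, also named in the title, was covered by 2 lists. Both tested members of the enterobactin list rose: entE, which activates the dihydroxybenzoate part of this iron-binding siderophore, 4.45-fold (log2 2.15 ± 0.13 SE; 163 ± 2.58 CPM against 36.5 ± 6.28 CPM, SD, n = 2 each), and entF, its serine-activating synthetase, 2.37-fold (log2 1.25 ± 0.13; 431 ± 85.1 against 182 ± 4.28 CPM). Their adjusted p-values were 1.04e-05 and 0.000223 (edgeR's quasi-likelihood test), and both also passed when adjusted over the list alone. Of the 33 genes on the ferric siderophore and iron uptake list, only 2 were tested under a symbol. Neither passed over all genes or when adjusted over the list alone, and no gene of ferric siderophore uptake was tested under its symbol. The 2 tested were feoA and feoB, parts of the ferrous iron transporter, at log2 changes of -0.34 ± 0.13 and -0.22 ± 0.11 (adjusted p = 0.09 and 0.18, edgeR's quasi-likelihood test). Both were lower with edgeR with total-count scaling (adjusted p = 0.0114 and 0.0161) and with the crossed pairing chosen after seeing the data (0.012 and 0.0417). Other alternatives also brought feoA or feoB past the threshold. The 2 enterobactin genes lay in a stretch of 14 neighbouring genes, all higher, from 540526 to 560178 (median log2 change 1.79, range 0.50 to 2.21). In the K-12 annotation, fepE and fepC follow entF, and entC and entB flank entE, but no symbols are given here to the other 12 genes of the stretch. Any siderophore uptake genes among them therefore rose without being counted in the list. These lists were taken from a title written on these samples, so their counts are not independent evidence.

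**Figure D1:**
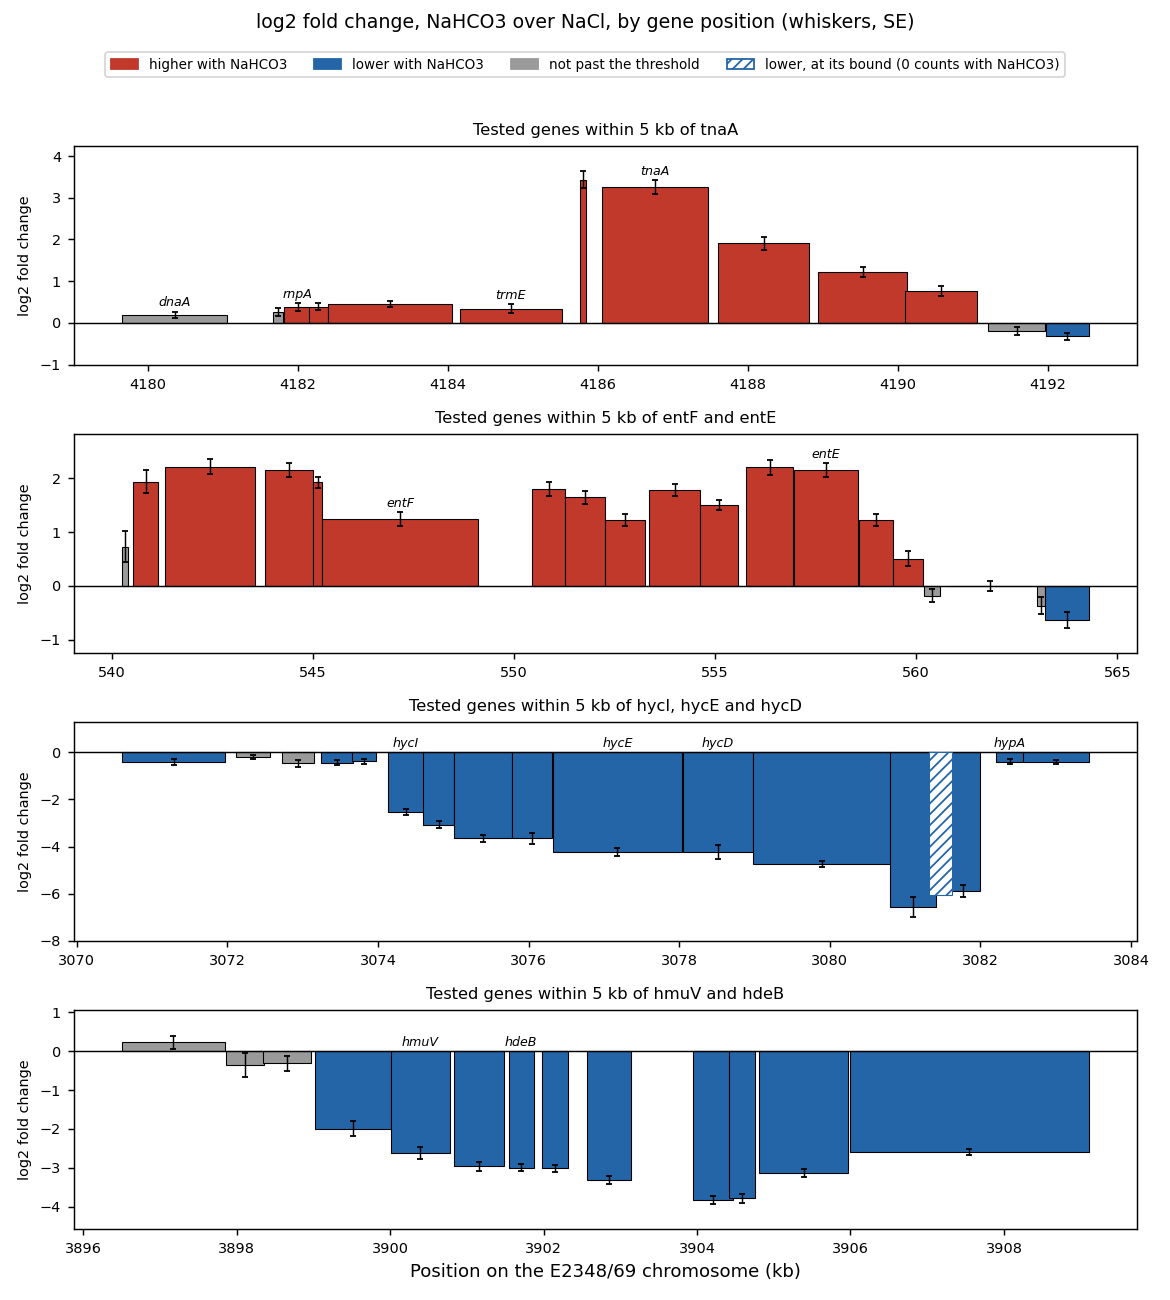
Bars show the log2 fold change of each tested gene (vertical axis, NaHCO3 over NaCl, 2 libraries per group) drawn to scale at its position in kb on the chromosome (horizontal axis), with whiskers for the SE. Red bars are genes higher and blue bars genes lower with NaHCO3, grey bars did not pass, and the hatched bar is a gene with 0 counts in both NaHCO3 libraries, drawn at its bound of 66.8-fold. The bars of tnaA (3.26) and entE (2.15) point up, and those of hycE (-4.25) and hdeB (-2.99) point down.

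The other genes among the 10 that rose most, of those with a symbol and at least 10 CPM in the higher group, belonged to several pathways. cysB, the activator of sulfate assimilation genes, rose by a log2 change of 1.56 ± 0.08 (SE), from 171 ± 4.84 to 504 ± 17.9 CPM (SD, n = 2 each). cpxP, a periplasmic regulator of the Cpx envelope stress response, rose by 1.08 ± 0.10, from 549.6 to 1159 CPM. nrdI, a flavodoxin used by a manganese ribonucleotide reductase, rose by 1.37, and mltD, a murein-cleaving transglycosylase, by 1.25. ilvM, a subunit of an acetohydroxyacid synthase of branched-chain amino acid synthesis, rose by 1.29, and hisG, the enzyme that begins histidine synthesis, by 1.27. sgbH, a sugar-acid phosphate decarboxylase, rose by 1.29 ± 0.27 from a low level of 4.46 ± 1.38 CPM. The adjusted p-values of these 7 genes lay between 4.44e-06 and 0.00749 (edgeR's quasi-likelihood test).

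Of the 10 genes that fell most, by the same limits, hycE, hycD, hycI, hdeB and hmuV lay in 2 stretches of the chromosome. In the first, 14 neighbouring genes from 3073243 to 3083437 were all lower, with a median log2 change of -3.65. It held hycE (3076326 to 3078035, minus strand), which fell from 185 ± 11.5 to 9.65 ± 2.72 CPM (SD, n = 2 each; log2 -4.25 ± 0.17 SE; adjusted p = 8.11e-07), hycD (62.5 ± 6.65 to 3.26 ± 2.27 CPM; log2 -4.24 ± 0.29, and -5.21 without NaHCO3 replicate 1) and hycI, the protease that matures the hydrogenase (log2 -2.53 ± 0.12). Next to hycD lay E2348C_RS16035, without a symbol, which fell by 4.75 on the log2 scale. E2348C_RS16045 (3081314 to 3081622) had 0 counts in both NaHCO3 libraries against 258 and 241 with NaCl, at least 66.8-fold lower with a floor of 3 counts per library. This gene overlaps neighbours on the other strand, and the use of strand in counting is not given in the sources used here, so its reads cannot be told from theirs. These loci without a symbol were chosen after their values were seen.

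In the second stretch, 16 neighbouring genes from 3899022 to 3917472 were lower, with a median log2 change of -2.79. Here hdeB (3901544 to 3901870, minus strand) fell from 505 ± 0.834 to 63.5 ± 1.59 CPM (log2 -2.99 ± 0.09; adjusted p = 2.4e-07, edgeR's quasi-likelihood test). It was 1 of 1 tested member of the glutamate acid resistance list, and it also passed when adjusted over the list alone. hmuV, annotated for the ATPase of a haem transporter, fell from 118 ± 8.39 to 19.2 ± 4.02 CPM (log2 -2.61 ± 0.15; adjusted p = 7.79e-06). hmuV ends 51 bp from a gene on the opposite strand that fell by 2.96 on the log2 scale, and the gene directly upstream on its own strand fell by 1.99, while the 4 genes before that one did not pass (log2 changes of -0.36 to 0.22).

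The remaining genes among these 10 act in anaerobic respiration, metal uptake and stress. nrfA, the periplasmic nitrite reductase, fell from 45.2 ± 7.76 to 9.75 ± 1.13 CPM (log2 -2.21 ± 0.17), within a stretch of 7 lower genes from 4630919 to 4639051 with a median of -1.71. nikC and nikD, the permease and an ATPase of the nickel transporter, fell by 1.31 and 1.25 on the log2 scale, within 6 neighbouring lower genes with a median of -1.16. iraD, an anti-adaptor that spares the sigma factor RpoS from degradation, fell by 1.87. narH, the iron-sulfur subunit of a nitrate reductase, fell by 1.23 at locus E2348C_RS08570. A paralog with the same symbol at E2348C_RS07180 fell by 0.73, and how reads shared by both were assigned is not given in the sources used here. The adjusted p-values of these 5 genes, with narH at the first locus, lay between 5.44e-05 and 0.00239 (edgeR's quasi-likelihood test).

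**Figure D2:**
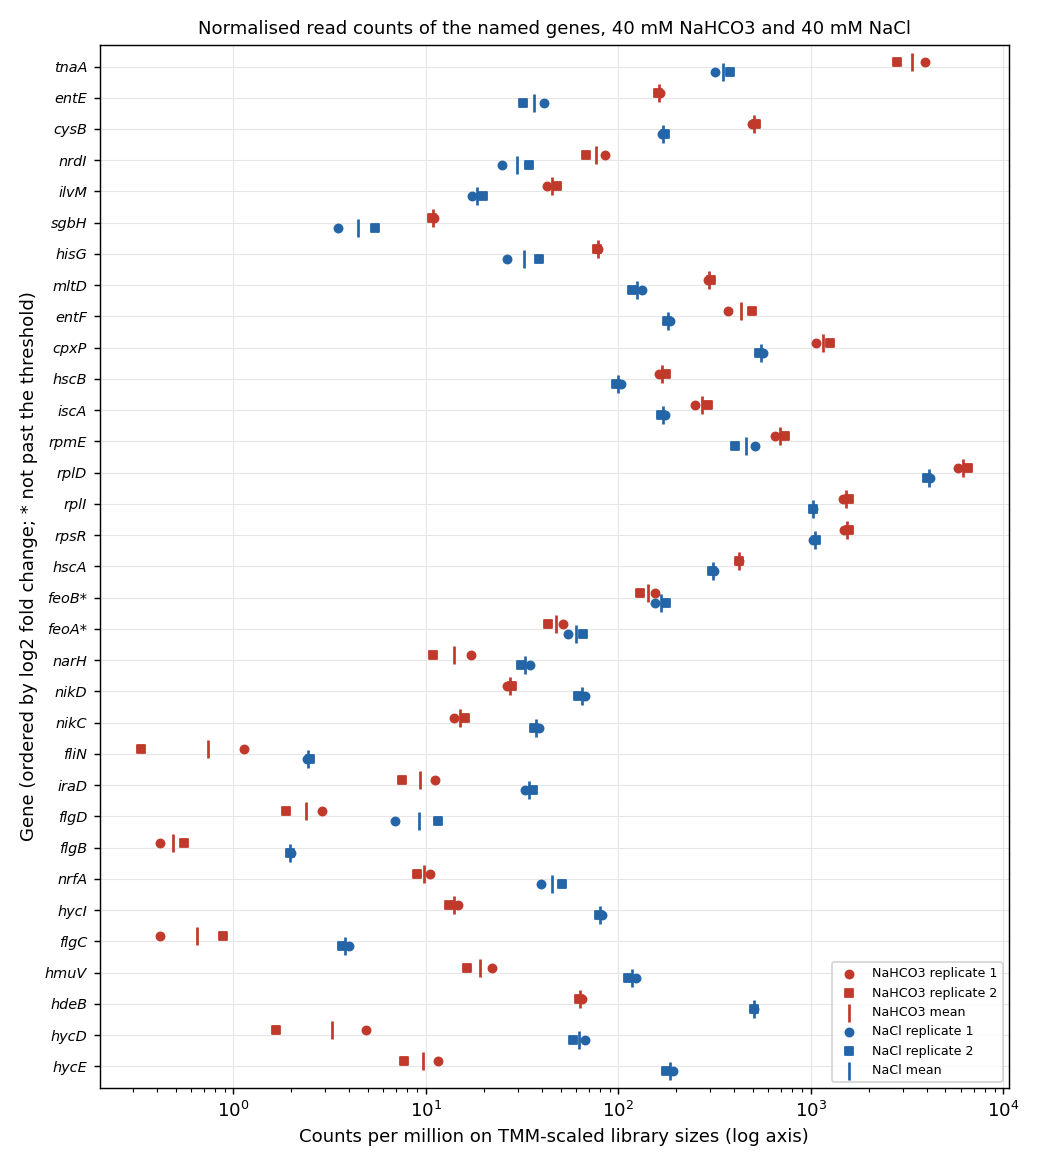
Each point is the normalised read count of a named gene in 1 library (horizontal log axis, CPM on TMM-scaled sizes), with genes ordered on the vertical axis by log2 fold change. Red marks are NaHCO3 libraries, blue marks NaCl libraries, circles and squares replicates 1 and 2, and vertical ticks group means. In tnaA the NaHCO3 mean of 3349 CPM lies above the NaCl mean of 349 CPM, and in hycE 9.65 CPM lies below 185 CPM.

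Among 22 gene lists with at least 3 tested members, 3 passed camera with a preset correlation of 0.01. List members came only from the 602 tested genes with a symbol, of which 167 were higher and 65 lower. Camera compared them with all 4835 tested genes, of which 759 were higher and 706 lower. How far this lean favoured lists called higher was not tested. Camera with an estimated correlation takes its degrees of freedom from the libraries, here 2 per group, so it has little power. A list that fails it is therefore neither kept nor refuted by it. Ribosomal protein genes were higher in 19 of 24 tested members (median log2 change 0.45; adjusted p = 1.18e-05 with the preset correlation, but adjusted p = 0.686 with an estimated correlation). Adjusted over the list alone, 21 were higher and 1 lower. The lower one was the locus with the symbol rpmJ at 282810 to 282950. Its level was low, at 8.51 ± 1.45 CPM with NaCl and 5.28 ± 0.13 CPM with NaHCO3 (SD, n = 2 each). rpmE rose by 0.59 ± 0.12 (SE), rplD by 0.58 ± 0.08, rplI by 0.57 ± 0.08 and rpsR by 0.56 ± 0.08. The level of rplD was 4102 ± 107 CPM with NaCl and 6147 ± 521 CPM with NaHCO3 (SD, n = 2 each). A stretch of 29 neighbouring genes from 3708769 to 3722713, among them rplD and rpsJ, was higher throughout, with a median of 0.44. The median change of the most abundant genes stood at 0.25, in a group that holds rplD and may hold further ribosomal genes without a symbol. With total-count scaling 13 of the 24 were higher and the median was 0.23.

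All 3 tested Isc genes, which assemble iron-sulfur clusters, rose. hscB, a co-chaperone, rose by 0.76 ± 0.09 on the log2 scale (SE, n = 2 per group). iscA, a cluster carrier, rose by 0.67 ± 0.10, and hscA, a chaperone, by 0.46 ± 0.08. The list passed camera at adjusted p = 0.0443 with the preset correlation (adjusted p = 0.686 with an estimated correlation), and 3 of 3 members passed when adjusted over the list alone. Of the 2 tested members of the Suf list, the other assembly system, sufC fell by 0.51 and sufA at -0.39 did not pass over all genes, while both were lower when adjusted over the list alone. The Isc list was no longer past the threshold without NaCl replicate 2 (adjusted p = 0.0773), with total-count scaling (0.0851) or with genes of a mean of at least 50 counts (0.0732).

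Flagella and chemotaxis genes were lower in 8 of 28 tested members and higher in 0, with 9 lower when adjusted over the list alone (median log2 change -0.64; camera adjusted p = 0.047). That set call was lost at adjusted p = 0.686 with an estimated correlation. flgC and flgB, parts of the flagellar rod, fell by 2.55 and 2.01 on the log2 scale, flgD, which caps the growing hook, by 1.94 and fliN, a part of the motor switch, by 1.70. Their levels were low, with flgD at 9.23 ± 3.32 CPM in NaCl and 2.39 ± 0.72 CPM in NaHCO3 (SD, n = 2 each) and flgB at 1.97 and 0.48 CPM. The adjusted p of flgB was 0.0158 with all libraries and 0.0801 without NaHCO3 replicate 1, and that of fliN 0.0397 and 0.21 without NaHCO3 replicate 2 (edgeR's quasi-likelihood test). The log2 change of fliN was -2.82 without NaHCO3 replicate 1 and -1.09 without NaHCO3 replicate 2, and that of flgC -3.16 without the latter. The list did not pass with total-count scaling (adjusted p = 0.117), with genes of a mean of at least 50 counts (0.254) or with a crossed pairing of the replicates, chosen after seeing the data (0.0564). With fry, 1 list passed, the transport of metals other than iron (adjusted p = 0.0317), which did not pass camera (0.0641, and adjusted p = 0.686 with an estimated correlation) nor fry without any 1 library (0.0777 to 0.333), with the replicate block (0.266) or with the crossed pairing (0.239). In this list nikC, nikD, nikE and zntA fell and znuC rose among 8 tested members, named after their values were seen, with 4 lower and 1 higher when adjusted over the list alone.

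**Figure D3:**
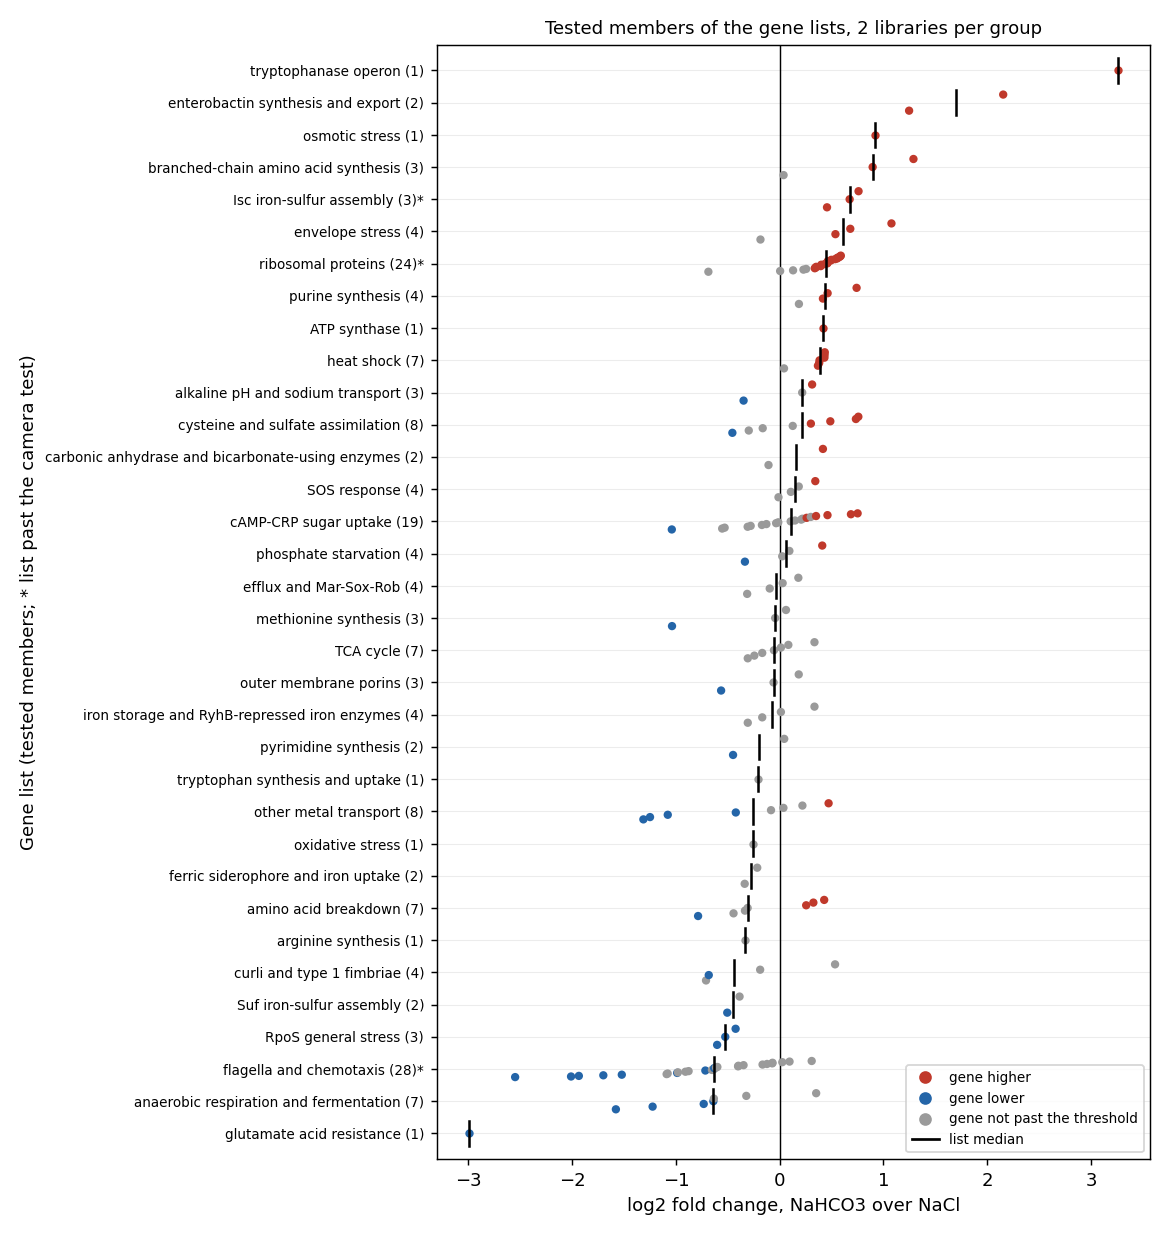
Each point is the log2 fold change of 1 tested gene (horizontal axis, NaHCO3 over NaCl) in its list (vertical axis, with the number of tested members), red where higher, blue where lower and grey where not past the threshold. Black ticks are list medians and asterisks mark the 3 lists past camera. The ribosomal protein median lies at 0.45, the Isc median at 0.67 and the flagella median at -0.64.

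In the authors' deposited table of their own test, 1655 genes were past a false discovery rate of 0.05. The sign of its log2 ratio was NaCl over NaHCO3, opposite to the one used here in each of the 1465 genes called here. Read in the direction used here, 825 of its genes were higher with NaHCO3 and 830 lower. Of the 1465 genes called here, 1452 were also past that level in the authors' deposited table, and the log2 ratio of tnaA there was -3.26.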

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

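The crossed pairing was chosen only after seeing the data, and the other alternatives before. Of the counts of genes, those with total-count scaling (358 higher, 1574 lower) and with a log2 change of at least 1 (104 and 149) lay outside 1.5 times 759 and 706. The first follows from the shift of all log2 changes by 0.21 and the second from its stricter threshold. Other alternatives gave 722 and 541 (DESeq2, with 287 genes given no adjusted p), 829 and 675 (DESeq2's size factors in edgeR), 766 and 710 (no filter) and 784 and 745 (mean of at least 50 counts). With a replicate block, 623 genes were higher and 601 lower, and 7 lists passed in place of 3. The added lists were heat shock (camera adjusted p = 0.0294), anaerobic respiration and fermentation (0.0294), purine synthesis (0.0342) and envelope stress (0.0342). Libraries with the same number did not deviate together (correlation across genes of -0.09 over all tested genes and -0.26 over the 3307 with a mean of at least 200 counts), so the numbers were not read as pairs. With replicate 1 of a group paired with replicate 2 of the other, 1037 genes were higher, 1008 lower and 2 lists passed. Leaving out each library gave 528 to 964 higher, 531 to 847 lower and 2 to 9 lists past camera, with 9 without NaHCO3 replicate 1 and 2 without NaCl replicate 2, and the lone library was assumed to vary like the other group. The lists past the threshold numbered 1 with total-count scaling and 1 with a mean of at least 50 counts. They numbered 0 with an estimated correlation and 1 with fry. With 2 libraries per group the estimated correlation leaves camera few degrees of freedom, which limits its power. The cause of the other counts was not tested. The counts of tna genes (1) and of higher iron genes (2) were the same under each alternative. Of the 1465 called genes, 0 were called in the opposite direction by edgeR or DESeq2 under any alternative. Over the 33 named genes, 348 of 357 alternative values kept their side of the threshold, 2 lost it (flgB and fliN, each without 1 NaHCO3 library), 7 gained it (feoA and feoB) and 0 reversed. Over the 22 lists, 202 of 219 kept it, 6 lost it, 11 gained it and 0 reversed. The gene tally leaves out the limit of a log2 change of at least 1. Among the called named genes, hscB, iscA, hscA, rpmE, rplD, rplI and rpsR did not reach it. Genes without an adjusted p in a setting are left out too. The list tally covers camera with the preset correlation alone, and DESeq2 gives no value for the list tests. With an estimated correlation 0 lists passed, and with fry only other metal transport. Fits without 1 library rest on the spread of the other group, so their calls are no stricter check. Alternatives set out for normalized values (pseudocount, filter on values, scaling of values, variance model) were not run because the table holds counts. Depth limits genes with few counts, such as flgB, with 4 and 5 counts in the NaHCO3 libraries.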

Other observations

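The tests on hmuV and on growth phase were chosen only after the results were seen, as were the members named in this part, while the test of ribosomal protein genes against abundance was fixed before its result was seen. Several lists that did not pass as sets held several called genes, with camera as the set test throughout. Over all tested genes, 759 of 4835 were higher and 706 lower. Among the 484 most abundant genes, 240 were higher and 35 lower. A count of higher genes among abundant members is therefore not by itself particular to a list. Of 7 tested heat shock genes, 6 rose (dnaK, groEL, groES, hslO, hslU and hflB, by log2 changes of 0.37 to 0.43; camera adjusted p = 0.0641), but with total-count scaling edgeR called 0 of the 7 (2 at an unadjusted p under 0.05). Of 4 envelope stress genes, cpxP, cpxA and pspB rose (median of the list 0.61; adjusted p = 0.0627), and of 4 purine synthesis genes purE, purN and purH rose (median 0.44; adjusted p = 0.0641). Of 3 branched-chain amino acid genes, ilvM and leuD rose (median 0.90; adjusted p = 0.101). cysM, cysW, cysN and cysJ of sulfate assimilation rose and tauD, for the use of taurine, fell among 8 (adjusted p = 0.22). All 3 tested RpoS general stress genes fell, treA, katE and treF, by -0.60 to -0.43 (adjusted p = 0.101). In anaerobic respiration and fermentation, 4 of 7 tested loci fell (nirD, narH at both loci and narI at 1 of its loci; adjusted p = 0.0641). The counts adjusted over the list alone were 6 higher for heat shock, 3 for envelope stress, 4 for purine synthesis, 2 for branched-chain amino acids, 4 higher and 1 lower for cysteine, 3 lower for RpoS, and 5 lower and 1 higher for the anaerobic list.

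Of 3 tested genes for alkaline pH and sodium transport, nhaR rose by 0.31 and nhaB fell by 0.35 (camera adjusted p = 0.937). The list of carbonic anhydrase and bicarbonate-using enzymes had 2 tested members, carB and purE. Of these purE rose, which is also on the purine synthesis list, and any link of that rise to the use of bicarbonate was not tested. Lists with 0 calls by edgeR were the TCA cycle (7 tested), iron storage and RyhB-repressed enzymes (4, all sdh genes), efflux (4), tryptophan synthesis (1), arginine synthesis (1) and oxidative stress (1). Together with the ferric siderophore list, of which only feoA and feoB were tested under a symbol, these 7 lists held 16 tested genes. Listed genes that carry no symbol in the annotation were not counted, so 0 calls in a list does not cover them. Of those 16, 5 had an unadjusted p under 0.05 with edgeR and 0 were called by DESeq2. For the lists of this paragraph the counts adjusted over the list alone were the same as over all genes, except that argD, of arginine synthesis, then passed as lower (-0.33). proX of osmotic stress (0.92) and atpC of ATP synthase (0.41) rose as the 1 tested member of each. Of the cAMP-CRP sugar list 5 of 19 rose, lamB and malE most (0.75 and 0.69), and glpA fell (adjusted p = 0.574). Single genes fell in the lists of methionine (metF, -1.04), porins (ompX, -0.56), pyrimidine (pyrE, -0.45) and surface fibres (fimA, -0.68), and recA rose among 4 SOS genes (0.34). Among 7 amino acid breakdown genes putA, gcvT and aspA rose and gabD fell, and among 4 phosphate starvation genes pstC rose and ugpC fell. Away from symbols, E2348C_RS12320 (2375584 to 2377575) rose 5.7-fold, from 144 ± 19.7 to 823 ± 66.8 CPM (SD, n = 2 each). Further stretches without any symbol fell from 1670150 to 1677836 (5 genes, median -2.94) and from 1020154 to 1029930 (10 genes on 1 strand, median -1.82).

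hmuV fell beside genes of the other strand that fell by about as much. Whether its same-strand unit fell stays open: the 5 genes upstream had a median log2 change of -0.32, with the adjacent one lower and 4 not past the threshold, and how far the unit reaches is not given. A candidate explanation is that reads from the convergent neighbour were counted for hmuV without regard to strand. It was formed from the values themselves, which therefore lend it no support: the gene next upstream had -1.99, and levels with NaCl were 308 CPM per kb in the convergent gene, 153 in hmuV and 35.5 in the next gene. It cannot be told apart here from a fall of hmuV with that gene or from transcription that truly runs into hmuV from the other side, because the use of strand is not given, and no biological explanation was tested.

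The rise of ribosomal protein genes may be part of a trend shared by abundant genes. In 10000 random lists of 24 genes matched on mean expression, the median log2 change was 0.27 (95% of lists between 0.13 and 0.39), and the ribosomal median of 0.45 lay at percentile 99.9 of them. The random genes were drawn singly, while rplD, rpsJ and other ribosomal genes lie in 1 stretch and may vary together. Only 24 of the 54 listed ribosomal protein genes were tested under a symbol. The matched genes may include ribosomal genes without one, so the trend may partly compare such genes with themselves. The percentile therefore cannot decide whether abundance is the whole cause, and the median of matched genes also lay above 0. With total-count scaling the list median was 0.23 and that of matched lists 0.05. Growth rate, which could differ between the arms, stays open and was not tested.

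The deep falls around hycE and around hdeB could reflect a difference in growth phase between the arms as well as bicarbonate. Oxygen supply and pH were not tested, and the NaCl arm was matched by its added salt. The RpoS list, a sign of the approach to stationary phase, had a median of -0.52, with 3 of 3 tested members lower, and 19 of 24 ribosomal protein genes were higher. A difference in growth phase and the treatment cannot be told apart here, because 3 RpoS genes are too few and no optical density per culture was used here.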
